A study of Homo sapiens with 67 samples.

How the data were processed

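The labels describe 67 samples, of which 25 libraries from HCT116 colorectal carcinoma cells were analysed. The other 42, chromatin immunoprecipitation and nucleosome mapping libraries from HCT116 and MCF7 cells, are not analysed here. The 25 libraries are 10 of 4sU-labelled RNA, which is newly made, and 15 of total RNA, which is steady-state RNA. The groups were 4sU control (n = 3), 4sU KO1 (n = 3), RNA control (n = 3), RNA KO1 (n = 3), RNA KO2 (n = 3), 4sU control 2 (n = 2), 4sU KO2 (n = 2), siNT (n = 3) and siKAP1 (n = 3). The labels give 25 nM and 72 h for siKAP1 and neither for siNT. The labels do not say that replicates come from separate cultures, so the p-values measure only the spread between these samples. Columns were matched to samples by name. The numbers in the names of the RNA KO2 columns were judged ambiguous, so these columns were matched to their group only and are called a, b and c in file order. The RNA control columns of the KO2 table held the same values as those of the KO1 table in 19802 of 19802 genes, so KO1 and KO2 share the same control libraries in steady-state RNA.

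The values were raw fragment counts per gene, made before deposit by featureCounts per the file headers. The headers name version 1.6.1, and 1.5.0 for the KO2 steady-state table. They describe paired ends, the reverse strand and whole gene spans of GENCODE release 27 on genome build hg38, introns included. The KO1 4sU table carries no such header. The submitters' processing notes name STAR 2.5.2b, Trim Galore 0.4.1, Bowtie2 2.3.2, SAMtools 1.6, FastQC 0.11.2, Picard 1.127, MACS2 2.1.0 and R 3.4.1 for the series. Genes are named by symbols alone, and positions are given as the files hold them. Of the 19802 genes, 18549 symbols (93.7%) stood in the reference annotation, and 2332 genes overlapped another gene on the same strand. Reads in an overlap cannot be given to 1 of the genes with certainty. Libraries held 46237680 to 93346098 counts in the KO1 4sU set and 69716743 to 122406033 in the KO2 4sU set. They held 46402725 to 65901927 in the RNA control and KO1 libraries, 37234170 to 61183319 in the RNA KO2 libraries and 16128497 to 19940567 in the siRNA set.

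Each comparison was fitted alone with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with the default expression filter, library sizes were scaled by TMM, and a quasi-likelihood F test was used because it carries the uncertainty of a dispersion estimated from few replicates. P-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, and a gene was called below an adjusted p of 0.05 with no fold change limit. A log2 fold change is given with its standard error. CPM gives counts scaled to the same library total after TMM scaling, as mean with SD over libraries, except where CPM of all counts is stated. Differences between effects were tested as interaction terms in a joint fit of the 4 groups. Calls "over the list alone" are adjusted within the members of a list.

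Where a group had 0 counts for a gene, the fold change is given as "at least", with that group set to 3 counts per library. Where a group held 1 to 3 counts in total, the ratio is given with an exact 95% interval. These floors and intervals cover counting error only. A gene's libraries do not overlap when every library of a group lies above every library of the other. By chance alone this happens for 10% of genes with 3 against 3 libraries and for 33.3% with 2 against 2.

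The 26 gene lists were written from general knowledge before the data were examined. They hold KRAB zinc finger genes, imprinted genes, germline and cancer-testis genes, p53 targets, TGF-beta and SMAD targets, WNT targets, MAPK output genes, immediate early genes, NF-kB targets, interferon-stimulated genes, pausing and elongation factors (among which stood the signalling genes SMAD2, SMAD3 and SMAD4 and the KAP1 relatives TRIM24 and TRIM33), silencing factors, cell cycle genes, MYC and ribosome biogenesis genes, hypoxia and glycolysis genes, stress response genes (integrated stress response and unfolded protein response), cholesterol synthesis genes, EMT genes, epithelial genes, intestinal genes, replication-dependent histone genes, mitochondrially encoded genes, ribosomal protein genes, and MCF7, fibroblast and immune marker genes. Lists were tested with camera (limma 3.58.1), which asks whether a list moves more than the other genes, at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. A list median is the median log2 fold change of its tested members. Genes with 0 counts in a group, set to their floor, leave the KRAB zinc finger medians of the 4 knockout comparisons unchanged at 0.43, 0.59, 0.41 and 0.50.

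Comparisons, alternatives, lists and the rule for naming genes were fixed before the data were examined. TRIM28, SMAD2 and CDK9 were always named. With them stood the 5 largest called rises and falls among genes of mean CPM at least 5 whose libraries do not overlap between the groups. Up to 4 members of a described list with the smallest p were named too. For differences between effects the 3 smallest p in each direction were taken, and for overlaps the 5 genes per direction with the largest smaller fold change. The lists described for each comparison, the minimum of 5 tested members, the gene length correction (removing from each library the lowess trend of its log2 CPM over log10 gene length, span 0.3), the thinning of counts to the depth of the siRNA set, the matched random lists, the simulation of shared controls and the comparison of siNT cells with the control of the clones were chosen after the data were seen.

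The alternatives were DESeq2 1.42.0 with its Wald test, RLE scaling, library sizes from ERCC synthetic RNAs, no filter, a filter at mean CPM 5, a 2-fold limit, the replicate number as a block, 1 fit over all libraries of an assay, and leaving out each library in turn. The procedure was tested on counts with known changes. Of genes shifted by a log2 fold change of 1, 87.9% were called in the KO1 nascent design, 94.0% in KO1 steady-state, 95.4% in KO2 steady-state, 59.7% in KO2 nascent, 95.4% in siKAP1, 76.1% for nascent minus steady-state, 35.8% for KO2 minus KO1 nascent, 80.3% for siKAP1 minus KO1 and 95.5% for KO2 against KO1. At a log2 fold change of 0.5 the lowest shares were 1.52% for KO2 minus KO1 nascent and 7.69% for KO2 nascent. For the lists, tested in the KO1 steady-state design alone, 5 of 5 shifted lists and 0 of 15 unchanged lists were called by camera. The simulated genes varied independently of each other, so this did not test the preset correlation between genes. No 2 libraries of the same group were duplicates, and pairs across groups were not compared. The smallest chi-square per degree of freedom between replicates was 3.36, for RNA KO1 replicates 1 and 2, and the largest was 247, for the 4sU control 2 pair. Effects of GC content were not tested because the genome sequence was not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.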

Results

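The study asked what loss of KAP1 does to transcription in HCT116 colorectal carcinoma cells. KAP1, encoded by TRIM28, is a corepressor that KRAB zinc finger proteins bring to DNA. Newly made RNA was read as 4sU-labelled RNA and steady-state RNA as total RNA. Knockout clone KO1 was compared with its controls in both assays (n = 3 each), as was clone KO2 (n = 3 in steady-state RNA, n = 2 in nascent RNA), and siKAP1 was compared with siNT in steady-state RNA (n = 3 each).

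TRIM28 itself (chromosome 19, 58544090 to 58550722, hg38) fell in every comparison. In CPM of all counts, the 3 4sU control libraries gave 361, 256 and 289, and the 4sU KO1 libraries 39.7, 41.2 and 44.3. The 4sU control 2 libraries gave 196 and 504 and the 4sU KO2 libraries 24.8 and 26.7. In steady-state RNA the controls gave 986, 961 and 982, KO1 36.3, 35.2 and 39.0, and KO2 111, 115 and 93.9. The siNT libraries gave 673, 619 and 651 and siKAP1 84.3, 72.3 and 75.0. The fitted log2 fold change of TRIM28 was −2.88 ± 0.14 (SE; adjusted p = 1.4e-06) in KO1 nascent RNA and −4.68 ± 0.04 (1.26e-32) in KO1 steady-state RNA. It was −3.26 ± 0.10 (1.18e-12) in KO2 steady-state RNA, −3.80 ± 0.51 (0.027, and 0.0615 with a stricter low count filter) in KO2 nascent RNA and −2.93 ± 0.08 (8.39e-13) after siKAP1. Clone KO2 kept more TRIM28 than KO1 in steady-state RNA (log2 1.42 ± 0.08, adjusted p = 1.17e-08).

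**Figure D1:**
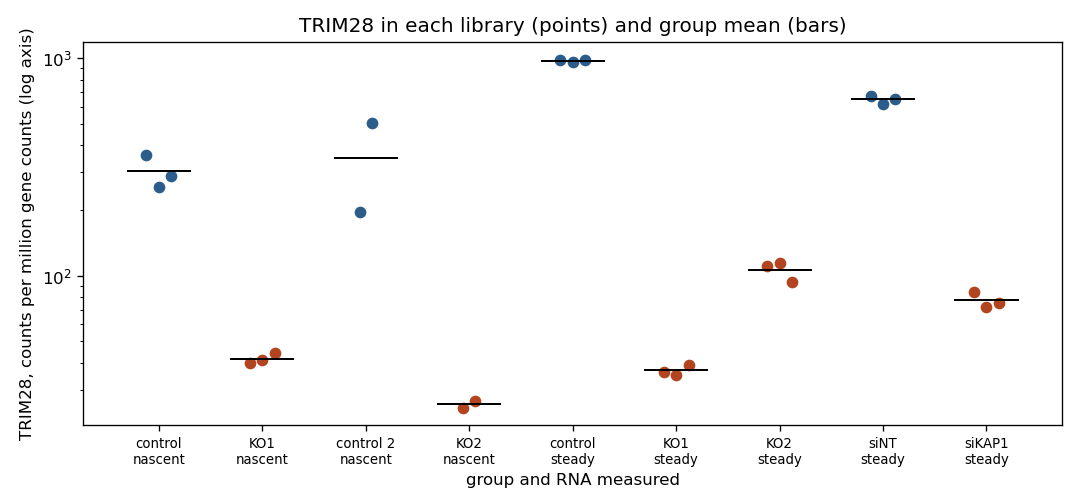
TRIM28 in CPM of all counts (log axis) for each library of the 9 groups, with points for libraries and bars for group means. The RNA control libraries stood at 986, 961 and 982, and the RNA KO1 libraries at 36.3, 35.2 and 39.0.

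In newly made RNA of clone KO1, genes that were near silence in control cells rose most. ACTL8 (chromosome 1, 17755312 to 17827063), an actin-like gene mostly expressed in testis, rose from 1.79 ± 0.157 to 374 ± 23.5 CPM (mean ± SD, n = 3 each; log2 7.71 ± 0.13, adjusted p = 3.53e-09). SPARC, a secreted matrix protein gene, rose from 0.0621 to 13.3 CPM (7.71 ± 0.21). ZNF595 (7.48 ± 0.26), the folate enzyme gene ALDH1L1 (6.79 ± 0.16) and the semaphorin and VEGF co-receptor gene NRP1 (6.31 ± 0.15, from 3.25 to 258 CPM) rose as well. LRP1B, a lipoprotein receptor gene on chromosome 2 (140231422 to 142131701), fell from 133 to 0.714 CPM (−7.51 ± 0.35), and the epithelial ETS factor gene EHF from 56.8 to 0.736 CPM (−6.28 ± 0.13). TIMP3 (−5.97 ± 0.19), LARGE1 (−5.58 ± 0.13) and PXDN (−4.73 ± 0.12) fell too. SMAD2 (−0.34, adjusted p = 0.134), a mediator of TGF-beta signalling, did not pass, and neither did CDK9 (0.02, 0.931), the kinase that releases paused polymerase. Without 4sU KO1 replicate 1 SMAD2 passed (−0.50, 0.0228), as it did after a correction for gene length (−0.30, 0.0346).

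Of 14258 tested genes, 2807 were called by edgeR, 1624 higher and 1183 lower. Scaling to ERCC synthetic RNAs shifted the median fold change by −0.51 and gave 304 higher and 2629 lower, so directions here are relative to the typical gene. ERCC counts, in CPM of gene counts, were 714 to 831 in 4sU controls and 809.9, 1326 and 1328 in 4sU KO1, so this shift rests on replicates 2 and 3. The libraries did not overlap in 5346 genes (37.5%, against 10% by chance). Without 4sU control replicate 3 the calls were 1747 and without 4sU KO1 replicate 2 they were 1662. The replicate number as a block gave 1622 calls (949 and 673) and a stricter low count filter 1531 (876 and 655). A 2-fold limit left 944.

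KRAB zinc finger genes, whose proteins recruit KAP1, were called as a group in KO1 nascent RNA: of 158 tested, 80 were higher, 6 lower and 72 not called (87 and 9 over the list alone), with a median log2 of 0.43 that became −0.09 with ERCC scaling. Camera gave an adjusted p = 2.07e-22, and an adjusted p = 0.0707 with an estimated correlation. ZNF569 (8.22 ± 0.25), ZNF266 (2.95 ± 0.11) and ZNF432 (4.08 ± 0.17, which overlaps ZNF841 on the same strand) were among the risers. Of the p53 targets, 25 of 38 rose, with 1 lower and 12 not called (29 and 1 over the list alone; median 0.64, and 0.13 with ERCC scaling, adjusted p = 1.18e-12, and adjusted p = 0.0229 with an estimated correlation). SPATA18, a mitochondrial quality control gene, rose by log2 4.91 ± 0.24, CDIP1 by 1.70 ± 0.14, the cytokine gene GDF15 by 1.77 ± 0.17 and the DNA repair gene DDB2 by 0.89 ± 0.09 (not called with ERCC scaling, 0.37, 0.265).

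Among signalling lists, WNT targets split in KO1 nascent RNA, with 7 of 23 higher, 7 lower and 9 not called (7 and 8 over the list alone; median −0.12, camera adjusted p = 0.0223, and adjusted p = 0.64 with an estimated correlation). BMP4 (−3.58 ± 0.15), SOX4 (−1.74 ± 0.10) and AXIN2 (−2.09 ± 0.12, overlapping AC004805.1) fell and the WNT antagonist gene DKK1 rose (1.33 ± 0.09). Interferon-stimulated genes had 19 of 46 higher, 3 lower and 24 not called (23 and 5 over the list alone). Their median of 0.34 became −0.17 with ERCC scaling, and the camera adjusted p was 0.0268 (0.0503 without 4sU control 3, 0.464 with an estimated correlation). CMPK2 (1.26 ± 0.13) and HERC5 (0.92 ± 0.12, not called with ERCC scaling, 0.43, 0.184) rose, while DDX60L (−1.45 ± 0.17) and DDX60 (−1.18 ± 0.16) fell.

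Cholesterol synthesis genes had 0 of 29 higher, 10 lower and 19 not called (0 and 10 over the list alone; median −0.22, camera adjusted p = 0.00729, and adjusted p = 0.464 with an estimated correlation). INSIG1 (−0.90 ± 0.10), FDFT1 (−0.80 ± 0.09), MSMO1 (−0.87 ± 0.13) and STARD4 (−0.75 ± 0.14) fell. STARD4 was not called in 1 fit over all libraries of the assay (−0.76, adjusted p = 0.0551). Epithelial genes had 14 of 41 higher, 0 lower and 27 not called (14 and 0 over the list alone). Their median of 0.13 became −0.39 with ERCC scaling, and the camera adjusted p was 0.0124 (0.055 with ERCC scaling, 0.64 with an estimated correlation). The keratin gene KRT80 rose by log2 2.31 ± 0.16, ELF3 by 1.32 ± 0.16, MAL2 by 0.67 ± 0.10 and E-cadherin gene CDH1 by 0.59 ± 0.10, the last 2 not called with ERCC scaling (0.17, 0.633 and 0.0737, 0.832). Pausing and elongation factors were not called as a group, with 3 of 41 higher and 1 lower (3 and 0 over the list alone; median −0.06, camera adjusted p = 0.975). The polymerase subunit gene POLR2A rose by log2 0.63 ± 0.11 (adjusted p = 0.00347; 0.0801 and 0.81 with ERCC scaling), while SMAD3 (0.48 ± 0.10, 0.00858) and HEXIM1 (0.41 ± 0.11, 0.0223) rose but became −0.03 and −0.12 with ERCC scaling. CTR9 was lower over all genes (−0.36 ± 0.11, 0.0399). The replicate number as a block ended the calls of HEXIM1 (0.0838) and CTR9 (0.119). So did leaving out 4sU control 1 or 3 or 4sU KO1 2 for HEXIM1 (0.0805, 0.121 and 0.115), and 4sU control 1, 2 or 3 or 4sU KO1 3 for CTR9 (0.104, 0.105, 0.132 and 0.0551). Replication-dependent histone genes had 6 of 44 higher and 0 lower (3 and 0 over the list alone), a median of 0.38 that became −0.19 with ERCC scaling, and a camera adjusted p = 0.0291 (adjusted p = 0.997 with an estimated correlation). That call was lost without 4sU control 2 or 3 (0.0567 and 0.0638) or 4sU KO1 2 or 3 (0.0968 and 0.322).

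The other lists were not called by camera in KO1 nascent RNA. Relative to the typical gene, median log2 and camera adjusted p were −0.14 and 0.143 for imprinted genes, 0.11 and 0.989 for germline genes, 0.14 and 0.975 for TGF-beta targets, 0.00 and 0.994 for MAPK output genes, 0.14 and 0.195 for immediate early genes, and 0.32 and 0.125 for NF-kB targets. They were −0.05 and 0.975 for silencing factors, −0.07 and 0.399 for cell cycle genes, 0.13 and 0.829 for MYC and ribosome biogenesis genes, −0.01 and 0.41 for hypoxia genes and 0.04 and 0.975 for stress response genes. EMT genes gave 0.06 and 0.324, intestinal genes 0.32 and 0.088, mitochondrially encoded genes 0.13 and 0.493, ribosomal protein genes 0.15 and 0.123 and MCF7 markers 0.00 and 0.735. Fibroblast markers (4 tested, median 0.70, 2 higher) and immune markers (2 tested, median 3.22, 2 higher) were too few for camera.

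In steady-state RNA of KO1, ZNF569 had 3 counts over the control libraries and 16.2 CPM in KO1 (ratio 857, 95% interval 293 to 4156). ZNF595 rose from 0.0381 to 16.3 CPM (log2 8.72 ± 0.16), SPARC by 8.16 ± 0.12, ACTL8 by 7.78 ± 0.06 and ALDH1L1 by 6.48 ± 0.18 (n = 3 each). LRP1B fell from 95.9 to 0.237 CPM (−8.66 ± 0.08), with further falls of LARGE1 (−6.09 ± 0.14), the glucose transporter gene SLC2A3 (−5.81 ± 0.12), EHF (−5.71 ± 0.09) and TMEM200A (−5.37 ± 0.12). CDK9 fell slightly (−0.35 ± 0.04, adjusted p = 7.85e-09) and SMAD2 did not pass (−0.01, 0.681). Of 13090 tested genes, 8922 were called by edgeR, 4407 higher and 4515 lower, and 1053 by at least 2-fold (372 and 681). The libraries did not overlap in 9222 genes (70.5%, against 10% by chance).

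In KO1 steady-state RNA, KRAB zinc finger genes had 101 of 143 higher, 18 lower and 24 not called (102 and 18 over the list alone; median 0.59, camera adjusted p = 1.34e-22, and adjusted p = 0.173 with an estimated correlation). ZNF266 rose by log2 3.66 ± 0.07 and ZNF850 by 2.78 ± 0.05. The p53 targets had 32 of 38 higher, 3 lower and 3 not called (32 and 3 over the list alone; median 0.50, adjusted p = 8.41e-11, and adjusted p = 0.202 with an estimated correlation). CDKN1A, the cell cycle inhibitor gene (chromosome 6, 36676459 to 36687339), rose from 90.9 to 208 CPM (1.20 ± 0.03), GDF15 by 1.32 ± 0.04, RPS27L by 1.04 ± 0.04 and MDM2, which encodes the ligase that degrades p53, by 0.76 ± 0.03. TGF-beta targets had 8 of 33 higher, 18 lower and 7 not called (8 and 18 over the list alone; median −0.18, adjusted p = 0.0336, and adjusted p = 0.33 with an estimated correlation). SERPINE1 (−3.10 ± 0.06), ID2 (−2.18 ± 0.05) and the pathway inhibitor gene SMAD7 (−2.65 ± 0.08) fell and BHLHE40 (1.64 ± 0.05) rose. WNT targets had 7 of 23 higher, 15 lower and 1 not called (7 and 15 over the list alone; median −0.31, adjusted p = 5.91e-05, and adjusted p = 0.173 with an estimated correlation). BMP4 (−3.38 ± 0.03), SOX4 (−1.52 ± 0.03), AXIN2 (−2.48 ± 0.06) and NOTUM (−3.22 ± 0.16) fell.

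EMT genes in KO1 steady-state RNA had 8 of 27 higher, 15 lower and 4 not called (8 and 15 over the list alone; median −0.18, camera adjusted p = 0.00025, and adjusted p = 0.261 with an estimated correlation). S100A4 (−4.26 ± 0.04, overlapping S100A3), TAGLN (−3.55 ± 0.05) and NT5E (−2.12 ± 0.04) were lower and SPARC higher. Epithelial genes had 28 of 41 higher, 9 lower and 4 not called (28 and 9 over the list alone; median 0.21, adjusted p = 0.000159, and adjusted p = 0.499 with an estimated correlation). KRT80 rose by 2.10 ± 0.03, ELF3 by 1.45 ± 0.04, CDH1 by 0.81 ± 0.03 and the desmosome gene DSC2 by 0.74 ± 0.04. Ribosomal protein genes had 71 of 75 higher, 0 lower and 4 not called (71 and 0 over the list alone; median 0.27, adjusted p = 1.04e-07, and adjusted p = 0.675 with an estimated correlation). RPL4 (0.50 ± 0.04) and RPL22 (0.41 ± 0.03) were among them, and the share of the list in all counts was 5.67 to 5.75% in KO1 against 4.71 to 5.04% in controls. Histone genes had 3 of 44 higher and 33 lower (median −0.29, adjusted p = 0.00313, and 0.737 with an estimated correlation), at 1.13 to 1.22% of counts against 1.43 to 1.58%. Camera also called imprinted genes (median −0.24, adjusted p = 0.0332, and 0.33 with an estimated correlation), interferon-stimulated genes (0.36, 0.0239, and 0.665), cell cycle genes (0.09, 0.0247, and 0.722) and MYC and ribosome biogenesis genes (0.21, 0.00869, and 0.712). The gene length correction ended the calls of histone genes (−0.13, 0.0584), TGF-beta targets (−0.14, 0.0531), interferon-stimulated genes (0.33, 0.0531) and cell cycle genes (0.0805, 0.0631) in KO1 steady-state RNA. ERCC scaling ended that of TGF-beta targets (0.0521), and the replicate number as a block those of TGF-beta targets (0.0779) and EMT genes (0.0514).

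In clone KO2, steady-state RNA showed some of the same leading genes beside changes of its own. The labels list no other steady-state control for KO2 than that of KO1. A difference between library sets, if any, cannot be told apart from the clone in this comparison. ACTL8 rose from 0.930 to 351 CPM (log2 8.55 ± 0.13), SPARC by 7.99 ± 0.17, ALDH1L1 by 6.54 ± 0.21, TM4SF18 by 6.14 ± 0.16 and NRP1 by 3.94 ± 0.11 (n = 3 each). LARGE1 (chromosome 22, 33162225 to 33922841) fell from 12.1 to 0.0477 CPM (−7.85 ± 0.21). Falls followed in LRP1B (−6.20 ± 0.17), the actin-binding protein gene TAGLN (−5.23 ± 0.10), CPA4 (−4.07 ± 0.10) and the AMPK subunit gene PRKAA2 (−3.78 ± 0.16). SMAD2 (−0.09, adjusted p = 0.324) and CDK9 (−0.09, 0.327) did not pass, but SMAD2 passed without RNA KO2 library c (−0.14, 0.0399) and CDK9 without library b (−0.16, 0.0472). Of 13300 tested genes, 7806 were called by edgeR, 4071 higher and 3735 lower, and 1547 by at least 2-fold (1074 and 473). The libraries did not overlap in 8709 genes (65.5%, against 10% by chance).

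Of the KRAB zinc finger genes, KO2 steady-state RNA had 85 of 140 higher, 17 lower and 38 not called (87 and 18 over the list alone; median 0.41, camera adjusted p = 1.11e-09, and adjusted p = 0.281 with an estimated correlation). ZNF736 rose at least 102-fold from 0 control counts, ZNF595 by log2 7.90 ± 0.22 and ZNF266 by 3.21 ± 0.10, while ZNF426 fell from 9.20 to 1.05 CPM (−3.14 ± 0.12). The p53 targets had 33 of 39 higher, 3 lower and 3 not called (33 and 3 over the list alone; median 0.71, adjusted p = 7.35e-13, and adjusted p = 0.0841 with an estimated correlation). SPATA18 rose by 5.34 ± 0.23, TP53INP1 by 2.04 ± 0.10, GDF15 by 1.79 ± 0.09 and CDKN1A from 94.7 to 270.1 CPM (1.51 ± 0.08). Cholesterol synthesis genes had 21 of 29 higher, 4 lower and 4 not called (21 and 4 over the list alone; median 0.62, adjusted p = 2.45e-05, and adjusted p = 0.281 with an estimated correlation). SQLE rose by 1.16 ± 0.07, FDFT1 by 1.21 ± 0.08, INSIG1 by 1.25 ± 0.09 and IDI1 by 1.25 ± 0.10.

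EMT genes in KO2 steady-state RNA had 13 of 28 higher, 14 lower and 1 not called (13 and 14 over the list alone; median −0.12, camera adjusted p = 0.00444, and adjusted p = 0.714 with an estimated correlation). TAGLN, S100A4 (−2.45 ± 0.09) and MYL9 (−2.12 ± 0.08) were lower and SPARC higher. Mitochondrially encoded genes had 1 of 13 higher, 11 lower and 1 not called (1 and 11 over the list alone; median −0.80, adjusted p = 1.12e-05, and adjusted p = 0.714 with an estimated correlation). MT-ATP8 (−1.47 ± 0.10, overlapping MT-ATP6), MT-ND5 (−1.15 ± 0.10), MT-CYB (−1.05 ± 0.10) and MT-CO1 (−1.07 ± 0.12) were lower. These genes held 3.22 to 3.75% of KO2 counts against 5.22 to 5.79% of control counts. Ribosomal protein genes had 67 of 74 higher, 0 lower and 7 not called (67 and 0 over the list alone; median 0.48, adjusted p = 5.78e-09, and adjusted p = 0.714 with an estimated correlation). RPL39 (1.64 ± 0.12), RPS29 (1.27 ± 0.10), RPL22 (1.11 ± 0.10) and RPL23A (1.14 ± 0.11) were among them. The list held 6.70 to 7.88% of KO2 counts against 4.71 to 5.04%. Camera also called histone genes (median −0.52, adjusted p = 0.000804, and 0.714 with an estimated correlation), immediate early genes (−0.25, 0.0438, and 0.714) and MYC and ribosome biogenesis genes (−0.15, 0.04, and 0.714). The gene length correction ended these 3 calls (−0.31 and 0.0591, −0.21 and 0.0945, −0.17 and 0.0591 in that order). Immediate early genes lost theirs also without RNA KO2 library a or c (0.0874 and 0.123), and MYC and ribosome biogenesis genes without a (0.128). Histone genes held 0.928 to 1.11% of KO2 counts against 1.43 to 1.58%. ERCC scaling was not run for KO2.

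Nascent RNA of clone KO2 showed large changes with only 2 libraries per group. ACTL8 rose from 1.02 to 478 CPM (log2 8.88 ± 0.30), ZNF736 by 8.72 ± 0.30, ZNF595 by 8.70 ± 0.27, CLEC2A by 7.81 ± 0.33 and STXBP6 by 7.51 ± 0.24 (n = 2 each; adjusted p = 0.00226 for ACTL8). LARGE1 fell from 49.7 to 0.235 CPM (−7.70 ± 0.25), with further falls of LRP1B (−5.89 ± 0.21), TMEM200A (−4.80 ± 0.21), TIMP3 (−4.70 ± 0.18) and ANO4 (−4.24 ± 0.25). SMAD2 (0.19, adjusted p = 0.484) and CDK9 (−0.48, 0.234) did not pass. Without control 2 replicate 1 they were 0.43 and −0.77, and without control 2 replicate 2 SMAD2 was −0.03. Such fits leave 1 library in a group, which has no spread of its own, so only sizes are given.

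Of 14405 tested genes in KO2 nascent RNA, 1205 were called by edgeR, 753 higher and 452 lower (62.5% higher), and 942 by at least 2-fold (587 and 355). The libraries did not overlap in 10578 genes (73.4%, against 33.3% by chance). The count and the balance depended on the processing, with 1375 higher and 1293 lower after a correction for gene length, 1435 and 1946 with DESeq2, 2175 and 2245 in 1 fit over all libraries of the assay, and 2239 and 2393 with the replicate number as a block. A stricter low count filter left 210 calls. Counts of calls without single libraries are not given, because such a fit leaves 1 library in a group and takes the spread from the other group.

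In KO2 nascent RNA, KRAB zinc finger genes had 51 of 159 higher, 1 lower and 107 not called (72 and 2 over the list alone; median 0.50, camera adjusted p = 3.82e-14, and adjusted p = 0.729 with an estimated correlation). ZNF610 rose by 3.68 ± 0.20 and ZNF569 by 5.80 ± 0.31. The p53 targets had 7 of 39 higher, 0 lower and 32 not called (19 and 0 over the list alone; median 0.49, adjusted p = 4.42e-07, and adjusted p = 0.729 with an estimated correlation). SPATA18 rose by 3.66 ± 0.29, EDA2R by 3.49 ± 0.28, RPS27L by 0.98 ± 0.13 and DRAM1 by 0.78 ± 0.12. Without 4sU KO2 1 or 2, which leaves 1 KO2 library, RPS27L (log2 0.96 and 1.00) and DRAM1 (0.77 and 0.81) kept their size and lost their calls. DRAM1 also lost its call with the stricter low count filter (adjusted p = 0.0575). Stress response genes had 0 of 37 higher, 3 lower and 34 not called (0 and 8 over the list alone; median −0.49, adjusted p = 0.000127, −0.28 and 0.016 after the gene length correction, and adjusted p = 0.729 with an estimated correlation). The amino acid synthesis genes PHGDH (−1.18 ± 0.12) and ASNS (−1.03 ± 0.15) and the glutathione-degrading enzyme gene CHAC1 (−1.04 ± 0.17) fell. Their calls were lost without 4sU KO2 1 or 2, which leaves 1 KO2 library. The log2 fold changes were then −1.18 and −1.16 for PHGDH, −1.07 and −0.98 for ASNS and −1.10 and −0.98 for CHAC1. ASNS also lost its call with the stricter low count filter (adjusted p = 0.0557), and CHAC1 became −0.47 (0.102) after the gene length correction.

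Short genes were lower as a whole in KO2 nascent RNA: genes under 10 kb had a median log2 of −0.49, those of 10 to 100 kb −0.01 and those over 100 kb 0.26. Of 74 ribosomal protein genes, edgeR called 0, also over the list alone (28 at unadjusted p under 0.05), and DESeq2 called 40 lower. They had a median of −0.72 (camera adjusted p = 5.46e-08, and adjusted p = 0.729 with an estimated correlation), which the gene length correction brought to −0.23 (0.016). RPS28 (−1.25, adjusted p = 0.0917), RPS2 (−1.11, 0.0968), RPLP0 (−1.24, 0.0988) and RPL36 (−1.19, 0.105, overlapping HSD11B1L) did not pass. All 4 passed with the replicate number as a block (2.42e-07 to 7.93e-05), in 1 fit over all libraries of the assay (0.0103 to 0.0153) and with DESeq2 (0.000191 to 0.000622). With only 4 libraries the block fit leaves little from which to estimate a gene's spread, and whether the numbers mark pairs is open. Without control 2 replicate 1 or 2, which leaves 1 control library, RPS28 was −1.66 and −0.69. RPS2 was then −1.49 and −0.61, and RPLP0 −1.67 and −0.65. Histone genes, short and intronless, had a median of −1.07 (0.000997, and 0.744 with an estimated correlation), and −0.13 (0.88) after the correction. The 4sU control 2 libraries differed from each other in ribosomal protein share (1.78 and 3.08%, against 1.51 and 1.55% in KO2) and histone share (0.153 and 0.421%). Cell cycle genes (median −0.35, camera adjusted p = 0.00446) and cholesterol synthesis genes (−0.34, 0.0121) were also called (0.729 for each with an estimated correlation), and became −0.23 (0.0309) and −0.25 (0.021) after the correction. KRAB zinc finger genes and p53 targets had medians of 0.56 and 0.61 after it.

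**Figure D2:**
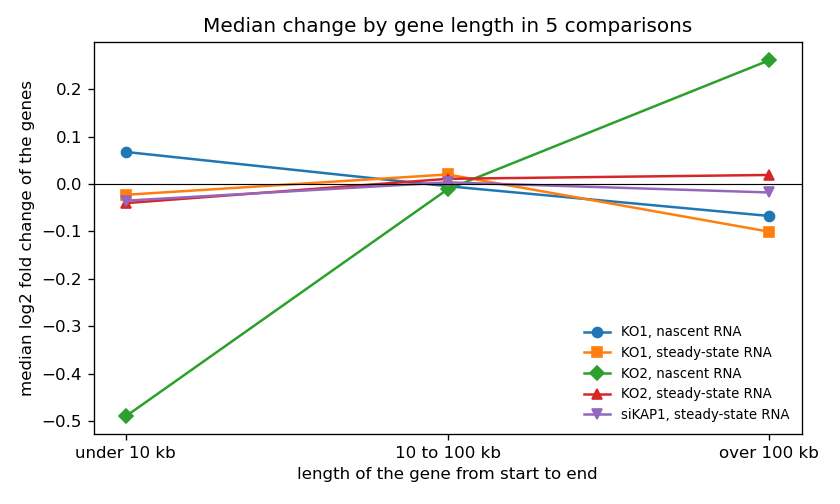
Median log2 fold change of genes under 10 kb, of 10 to 100 kb and over 100 kb for the 2-group comparisons, with points for bins. KO2 nascent RNA went from −0.49 in the shortest genes to 0.26 in the longest.

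After 72 h of siKAP1 other genes led. MYBPH had 2 siNT counts and 21.5 CPM after siKAP1 (ratio 576, 95% interval 159 to 4765). The secretory granule genes SCG2 (from 16.1 to 226 CPM, log2 3.82 ± 0.08) and VGF (3.03 ± 0.10), the carboxypeptidase gene CPA4 (2.73 ± 0.14) and the drug efflux pump gene ABCB1 (2.36 ± 0.10) rose (n = 3 each). CHAC1 fell from 47.4 to 4.82 CPM (−3.31 ± 0.14) and the asparagine synthetase gene ASNS from 219.96 ± 73.9 to 27.1 ± 3.08 CPM (−3.02 ± 0.18). ARRDC4 (−3.16 ± 0.20) and SGPP2 (−2.54 ± 0.16) fell too. SMAD2 (0.20 ± 0.06, adjusted p = 0.0167) and CDK9 (0.22 ± 0.08, 0.027) were slightly higher relative to the typical gene, and lower with ERCC scaling (−2.10 and −1.90). SMAD2 lost its call without siNT 3 (0.0627), siKAP1 2 (0.0653) or siKAP1 3 (0.0567), and CDK9 without siNT 2 (0.0932), siNT 3 (0.0888), siKAP1 1 (0.103) or siKAP1 3 (0.0683). Of 12908 tested genes, 6958 were called by edgeR, 3346 higher and 3612 lower, and 838 by at least 2-fold (187 and 651). The libraries did not overlap in 7636 genes (59.2%, against 10% by chance). ERCC counts, in CPM of gene counts, were 33.9 to 541 in siNT and 74.3, 5945 and 6434 in siKAP1. Scaling to them shifted the median by −2.22 and left 0 calls by edgeR (6 genes at unadjusted p under 0.05) and 35 by DESeq2 (959 unadjusted). The siNT libraries themselves held 37.9, 33.9 and 541, so whether the spike-in was added in equal amount is unknown, and every ERCC-scaled value of this comparison rests on that.

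After siKAP1, KRAB zinc finger genes were not called as a group: 10 of 121 were higher, 38 lower and 73 not called (9 and 36 over the list alone; median −0.15, camera adjusted p = 0.238), with ZNF195 (−0.64 ± 0.07), ZNF483 (−0.84 ± 0.10) and ZNF699 (−0.90 ± 0.13) lower and ZNF425 higher (0.78 ± 0.12, but −1.39 with ERCC scaling). The p53 targets went down, with 5 of 37 higher, 21 lower and 11 not called (6 and 21 over the list alone; median −0.29, adjusted p = 0.000363, and adjusted p = 0.256 with an estimated correlation). CDKN1A fell from 210 to 70.1 CPM (−1.58 ± 0.07), and so did TP53INP1 (−1.54 ± 0.08), DDB2 (−1.39 ± 0.09) and FDXR (−0.99 ± 0.07). Interferon-stimulated genes had 3 of 45 higher, 24 lower and 18 not called (3 and 25 over the list alone; median −0.37, adjusted p = 0.00285, and adjusted p = 0.271 with an estimated correlation). IFITM2 (−0.83 ± 0.08, overlapping IFITM1), OAS3 (−0.77 ± 0.08), IFIT1 (−1.27 ± 0.13) and USP18 (−1.30 ± 0.15) fell. Stress response genes had 1 of 36 higher, 24 lower and 11 not called (2 and 24 over the list alone; median −0.35, adjusted p = 2.82e-09, and adjusted p = 0.331 with an estimated correlation). PHGDH (−2.14 ± 0.11) and DDIT4 (−1.76 ± 0.11) fell beside CHAC1 and ASNS. Epithelial genes had 2 of 41 higher, 34 lower and 5 not called (3 and 34 over the list alone; median −0.70, adjusted p = 4.57e-13, and adjusted p = 0.271 with an estimated correlation). The epithelial master regulator gene GRHL2 (−1.58 ± 0.08), ST14 (−1.66 ± 0.08), AP1M2 (−1.37 ± 0.09) and PKP3 (−1.26 ± 0.09) fell.

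Pausing and elongation factors had 23 of 41 higher, 7 lower and 11 not called after siKAP1 (23 and 7 over the list alone), with a median of 0.22 that became −2.07 with ERCC scaling and a camera adjusted p = 0.0063 (0.0584 with ERCC scaling, 0.271 with an estimated correlation). The elongation complex genes CTR9 (1.06 ± 0.06), NELFCD (0.67 ± 0.07), AFF4 (0.55 ± 0.07) and SUPT5H (0.56 ± 0.08) were higher, and lower with ERCC scaling. Mitochondrially encoded genes were higher in 13 of 13 (13 and 0 over the list alone), with a median of 0.86 that became −1.39 with ERCC scaling (adjusted p = 4.01e-14, and 0.271 with an estimated correlation). MT-ND2 (1.59 ± 0.08), MT-ND3 (1.54 ± 0.09), MT-ND5 (0.98 ± 0.09) and MT-ND1 (0.89 ± 0.08) were higher, and lower with ERCC scaling, and the mitochondrial share was 12.3 to 12.9% of counts in siKAP1 and 7.24 to 8.78% in siNT. Histone genes had 1 of 37 higher and 35 lower (median −0.62, adjusted p = 1.12e-11, −0.36 and 0.000145 after the gene length correction, and 0.331 with an estimated correlation), at 0.311 to 0.342% of counts against 0.493 to 0.544%. Camera also called ribosomal protein genes (median 0.31, and −1.81 with ERCC scaling, adjusted p = 4.7e-12, and 0.48 with an estimated correlation), MYC and ribosome biogenesis genes (0.27, and −1.94 with ERCC scaling, 0.000202, and 0.275) and intestinal genes (0.23, and −1.86 with ERCC scaling, 0.0257, and 0.48). Hypoxia and glycolysis genes (−0.30, 0.00285, and 0.636) and cholesterol synthesis genes (−0.11, 0.0397, and 0.636) were lower, but not called with ERCC scaling (0.0785 and 0.307). Cholesterol synthesis genes lost their call without siNT 1 (0.0847) or siKAP1 2 (0.0726), and intestinal genes without siNT 2 (0.056) or siKAP1 1 (0.0782).

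**Figure D3:**
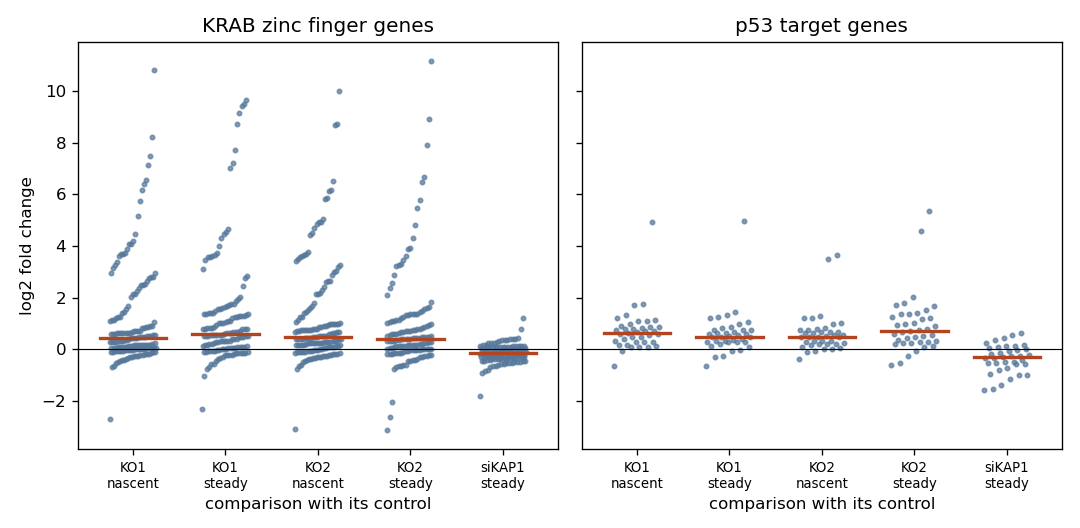
Log2 fold change of each tested KRAB zinc finger gene and p53 target in the 2-group comparisons, with points for genes and bars for medians. KRAB medians were 0.43 in KO1 nascent RNA (−0.09 with ERCC scaling), 0.59, 0.41 and 0.50 in the other knockout comparisons and −0.15 after siKAP1, and p53 medians 0.64, 0.50, 0.71, 0.49 and −0.29.

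The siKAP1 effect differed from the KO1 effect in steady-state RNA in 7586 of 13594 genes by edgeR (4164 higher, 3422 lower, and 1721 by at least 2-fold). The siKAP1 effect minus the KO1 effect was positive for LRP1B (log2 7.88 ± 0.15), VCAN (6.28 ± 0.10) and EHF (6.01 ± 0.11). It was negative for CDKN1A (−2.75 ± 0.08, adjusted p = 4.38e-16), ZNF595 (−8.76 ± 0.26) and the hyaluronan synthase gene HAS3 (−2.39 ± 0.07). LRP1B itself fell after siKAP1 (34.4 to 19.7 CPM), less than in KO1, and ZNF595 changed little there (4.91 to 4.57 CPM). Higher and lower below refer to this difference of effects. TRIM28 was higher by 1.77 ± 0.08 (1.24e-12), SMAD2 by 0.24 (0.0041) and CDK9 by 0.59 (7.23e-06). The KRAB zinc finger genes were lower in 90 of 138 and higher in 15 (91 and 15 over the list alone; median −0.65, camera adjusted p = 2.93e-13, and adjusted p = 0.0956 with an estimated correlation). The p53 targets were lower in 30 of 38 and higher in 5 (31 and 5 over the list alone; median −0.84, adjusted p = 4.15e-15, and adjusted p = 0.00632 with an estimated correlation). Epithelial genes were lower in 33 of 41 and higher in 2 (34 and 2 over the list alone; median −0.90, adjusted p = 3.1e-16, and adjusted p = 0.0956 with an estimated correlation). Interferon-stimulated genes were lower in 30 of 48 and higher in 6 (median −0.72, adjusted p = 4.06e-05, and adjusted p = 0.143 with an estimated correlation). Mitochondrially encoded genes were higher in 13 of 13 (median 0.87, 4.06e-05, and 0.611 with an estimated correlation). WNT targets (0.21, 0.0024, and 0.611 with an estimated correlation), cell cycle genes (−0.20, 0.00139, and 0.673) and stress response genes (−0.39, 0.000452, and 0.611) were called too. Method, time and library set changed together between these groups, so the difference cannot be given to any of them.

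KO1 changed nascent and steady-state RNA to different extents in 1977 of 14122 genes by edgeR (931 higher, 1046 lower, and 284 by at least 2-fold, 239 and 45). The balance depended on the processing, with 968 higher and 855 lower under RLE scaling, 62.3 to 67.7% higher without a 4sU control library and 59.8 to 66.6% higher without a 4sU KO1 library. The replicate number as a block left 659 calls (346 and 313). The nascent effect was higher for the endocytosis gene EPN1 (log2 1.62 ± 0.11), FGD1 (2.04 ± 0.14) and NT5E (1.36 ± 0.10, adjusted p = 6.93e-06) and lower for ALDH1A3 (−1.02 ± 0.08), ZNF566 (−1.23 ± 0.10) and ZNF808 (−1.12 ± 0.09, overlapping ZNF701). TRIM28 fell less in nascent RNA (1.74 ± 0.14, 9.37e-06). SMAD2 (−0.38, 0.131) and CDK9 (0.32, 0.112) did not pass, but did without 4sU KO1 1 (−0.45, 0.0181 and 0.47, 0.0156) and after the gene length correction (−0.38, 0.0107 and 0.26, 0.0208), and CDK9 also without 4sU control 1 (0.46, 0.043). KRAB zinc finger genes had 1 of 156 higher and 53 lower (4 and 65 over the list alone; median −0.35, camera adjusted p = 7.09e-14, and adjusted p = 0.0324 with an estimated correlation). They thus rose more in steady-state RNA relative to the typical gene of each assay. EMT genes had 8 of 30 higher and 1 lower (9 and 1 over the list alone; median 0.30, adjusted p = 2e-06, and adjusted p = 0.0324 with an estimated correlation). Cell cycle genes (0 of 56 higher, 19 lower, median −0.20, adjusted p = 1.18e-07, and 0.105 with an estimated correlation) and cholesterol synthesis genes (1 of 29 higher, 9 lower, −0.28, 6.22e-06, and 0.105) were lower. Histone genes (0.65, 1.64e-09, and 0.506), TGF-beta targets (0.22, 0.00291, and 0.453) and WNT targets (0.19, 0.0135, and 0.371) were higher, and ribosomal protein genes (−0.19, 4.42e-05, and 0.819) and MYC and ribosome biogenesis genes (−0.18, 0.00291, and 0.453) lower. Ribosomal protein genes and MYC and ribosome biogenesis genes were not called without 4sU control 1 (0.0892 and 0.0687) or 4sU KO1 1 (0.144 and 0.106), nor WNT targets without 4sU KO1 3 (0.0607). Single libraries moved the number of calls: it was 1085 without 4sU control 3, 2977 without 4sU KO1 1, 1081 and 1049 without RNA control 1 and 2, and 1305, 1071 and 1022 without RNA KO1 1, 2 and 3.

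KO2 and KO1 differed in their effect on nascent RNA in 623 of 14730 genes by edgeR (362 higher, 261 lower, and 495 by at least 2-fold). The syntaxin-binding gene STXBP6 (log2 10.56 ± 0.53, adjusted p = 2.58e-05, with 4 counts in 4sU KO1), EHF (3.27 ± 0.19, 4.53e-05) and the potassium channel gene KCNH8 (7.81 ± 0.51, 6.77e-05) were higher for KO2, and the mucin gene MUC16 (−3.47 ± 0.24), the plasminogen activator gene PLAT (−1.83 ± 0.18, 0.00059) and WNT9A (−1.84 ± 0.18) lower. TRIM28 was not called (−0.83, 0.178), and was −1.33 without control 2 replicate 1, which leaves 1 library in that group. SMAD2 (0.59, 0.162) and CDK9 (−0.42, 0.234) were not called either, and were 0.91 and −0.66 without that library. CDK9 became 0.0735 (0.684) after the gene length correction. Calls were 237 with the replicate number as a block (166 and 71), 259 with a stricter low count filter, 1405 after the gene length correction (625 and 780) and 2653 with DESeq2 (1114 and 1539). Camera called epithelial genes (0 of 41 higher, 6 lower, 0 and 17 over the list alone, median −0.60, adjusted p = 1.42e-07) and interferon-stimulated genes (2 of 50 higher, 7 lower, 5 and 18 over the list alone, −0.48, 0.00199). It called stress response genes (0 of 37 called by edgeR, 22 at unadjusted p under 0.05, 1 higher and 16 lower by DESeq2, 1 and 16 over the list alone, −0.48, 0.000187), ribosomal protein genes (0 of 74 called by edgeR, 66 unadjusted, 45 lower by DESeq2, 0 and 63 over the list alone, −0.82, 7.96e-15), histone genes (−1.43, 3.47e-09) and immediate early genes (−0.39, 0.00555) too. The gene length correction ended the call of immediate early genes (−0.0356, 0.516). Without control 2 replicate 1, which leaves 1 library in that group, they kept their median (−0.42) and lost the call. The gene length correction brought stress response genes to −0.26 (0.0159), ribosomal protein genes to −0.32 (6.12e-05) and histone genes to −0.38 (0.0159). Camera called 0 lists with an estimated correlation (2 at unadjusted p under 0.05). KRAB zinc finger genes (0.11, 0.502) and p53 targets (−0.07, 0.523) were not called as groups. The number of calls was 293 and 269 without 4sU control 2 and 3 of the KO1 set, and 1495, 305 and 407 without 4sU KO1 1, 2 and 3. Leaving out a library of the KO2 set leaves 1 in its group, so those counts are not given.

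In steady-state RNA, KO2 differed from KO1 in 7604 of 13295 genes by edgeR (4267 higher, 3337 lower, and 1444 by at least 2-fold, 1234 and 210). The balance depended on the processing, with 3658 higher and 3824 lower by DESeq2, 4023 and 4112 after the gene length correction and 3964 and 3734 under RLE scaling. The KO2 libraries have no steady-state control of their own, so a difference between library sets cannot be told apart from the clone. The proteoglycan gene VCAN (from 1.83 to 30.7 CPM, log2 4.07 ± 0.12), the glutamate receptor gene GRIN2B (3.89 ± 0.12), TNIK (3.76 ± 0.09), TM4SF18 (3.69 ± 0.14) and PDE4B (3.56 ± 0.10) were higher in KO2 (n = 3 each). KRT80 (−3.29 ± 0.08), ZNF569 (−3.13 ± 0.12), the tissue factor gene F3 (−2.79 ± 0.08), KRT7 (−3.99 ± 0.10, overlapping KRT86) and ARPC1B (−4.17 ± 0.13, overlapping AC004922.1) were lower. CDK9 was higher (0.26, adjusted p = 0.00977), and not called without RNA KO1 1, 2 or 3 (0.0591, 0.0552 and 0.0624). SMAD2 was not called (−0.07, 0.432), except without RNA KO2 library c (−0.14, 0.0435). The libraries did not overlap in 8557 genes (64.4%, against 10% by chance). Cholesterol synthesis genes had 20 of 29 higher and 0 lower (21 and 0 over the list alone; median 0.62, camera adjusted p = 9.01e-07, and adjusted p = 0.407 with an estimated correlation). INSIG1 was higher by 1.39 ± 0.09, FDFT1 by 1.19 ± 0.08, IDI1 by 1.44 ± 0.10 and SQLE by 0.91 ± 0.07. MYC and ribosome biogenesis genes had 1 of 44 higher and 32 lower (1 and 33 over the list alone; median −0.37, adjusted p = 1.1e-06, and adjusted p = 0.492 with an estimated correlation). BYSL (−0.65 ± 0.07), RRP1B (−0.66 ± 0.07), SRM (−0.78 ± 0.09) and RRP12 (−0.77 ± 0.09) were lower. Epithelial genes had 10 of 41 higher and 26 lower (median −0.34, adjusted p = 1.62e-06, and adjusted p = 0.492 with an estimated correlation). KRT20 (−2.80 ± 0.18) and CLDN7 (−1.02 ± 0.09, overlapping AC003688.1) were lower. KRAB zinc finger genes (21 of 148 higher, 66 lower, −0.14, 0.000129, and 0.407 with an estimated correlation) and mitochondrially encoded genes (−0.74, 9.01e-07, and 0.492) were called by camera too. So were cell cycle genes (−0.26, 2.62e-05, and 0.574), immediate early genes (−0.30, 0.000129, and 0.527), WNT targets (0.25, 0.0257, and 0.527) and ribosomal protein genes (0.22, 0.0227, and 0.801, but 0.0548 without RNA KO2 library b).

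The comparisons shared many calls. KO1 nascent and steady-state RNA shared 1025 higher genes (476 expected by chance over 13037 genes) and 979 lower genes (378 expected), with 60 and 27 in opposite directions and a correlation of fold changes of 0.853. LRP1B (−7.51 and −8.66), ZFP28 (at least 47.4-fold and at least 77.5-fold) and ZNF736 (at least 81.5-fold and at least 26.3-fold) were among the largest, with the T cell adhesion gene CD2 (ratio 408, 95% interval 72.7 to 16157, and at least 27.7-fold). In steady-state RNA, KO1 and KO2 shared 2078 higher genes (1299.5 expected) and 2173 lower genes (1293 expected), with 621 and 641 opposite (1257 and 1336 expected), and r was 0.637. Both used the same 3 control libraries, too few to split, and part of this excess may come from them. In 50 simulations without any effect r was 0.430 (0.407 to 0.470). The covariance was then 0.00536 against 0.374 observed. Same-direction calls by edgeR were 0 against 4251, but hardly any gene was called there (median 2 for KO1 and 0 for KO2). That 0 was thus fixed in advance and does not measure the part of the sharing that comes from the controls. Clones with effects of their own were not simulated. Nascent RNA of KO1 and KO2, with separate controls, shared 415 higher (79.3 expected) and 319 lower genes (36.8 expected), with 6 and 22 opposite and r of 0.619. KO2 nascent and steady-state RNA shared 560 higher (195 expected) and 309 lower genes (115 expected), with 8 and 27 opposite and r of 0.689.

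KO1 and siKAP1 shared 1384 higher genes (1125 expected) and 1533 lower genes (1232 expected), with 1026 and 977 opposite (1199 and 1157 expected) and r of 0.117. With a 2-fold limit, 13 and 120 were shared (3.59 and 27.9 expected). Opposite genes then exceeded chance too, with 38 higher in KO1 and lower after siKAP1 (13.4 expected) and 23 the reverse (7.47 expected). The shared risers were led by the retinal reductase gene DHRS3 (2.35 ± 0.04 in KO1 and 2.02 ± 0.08 after siKAP1), NRP1 (5.38 ± 0.05 and 1.95 ± 0.10), CEACAM1 (2.71 ± 0.20 and 1.93 ± 0.18), HOXA1 (1.45 ± 0.10 and 1.42 ± 0.12) and SPARC (8.16 ± 0.12 and 1.40 ± 0.19). Shared falls were led by SLPI, TRIM28, FOXQ1, COL15A1 (−3.90 ± 0.44 and −2.69 ± 0.32) and SGPP2 (−2.33 ± 0.22 and −2.54 ± 0.16). SLPI, FOXQ1 and COL15A1 held few counts in the lower group, 8, 3 and 5 in KO1 and 3, 10 and 14 after siKAP1. All 4 knockout comparisons called 293 genes higher and 241 lower of 12960 tested in each. Among the 293 were ZFP28, ZNF736, CD2, ACTL8 and LCN9 (at least 58.9-fold in KO1 nascent RNA), and among the 241 were LRP1B, LARGE1, TTC22 (at least 20.3-fold lower in KO1 steady-state RNA), RSPO1 (at least 11.6-fold lower there) and HTR1B (at least 10.6-fold lower in KO2 steady-state RNA). After siKAP1, 248 of the higher genes were tested, with 37 higher and 103 lower (median −0.20), and 231 of the lower genes, with 112 lower and 48 higher (median −0.28).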

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

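The tests of sample mixing in control 2, of slower proliferation and of differences between replicate libraries were chosen only after the results they measure were seen.

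Results stand here when a test showed that an effect differed between clones, assays or methods, or when a signal appeared in spike-in counts that the comparisons do not use. The KO1 effect differed between nascent and steady-state RNA in 1977 genes by the interaction test. The KO2 and KO1 effects on nascent RNA differed in 623 genes by the same test, with STXBP6 (10.56), KCNH8 (7.81) and EHF (3.27) higher for KO2 and MUC16 (−3.47), WNT9A (−1.84) and PLAT (−1.83) lower. The siKAP1 and KO1 effects differed in 7586 genes. The siKAP1 effect minus the KO1 effect was positive for LRP1B (7.88), VCAN (6.28) and EHF (6.01) and negative for ZNF595 (−8.76), CDKN1A (−2.75) and HAS3 (−2.39). Between these effects the list medians were −0.65 for KRAB zinc finger genes, −0.84 for p53 targets and −0.90 for epithelial genes. Clones KO2 and KO1 differed directly in 7604 genes in steady-state RNA, with VCAN (4.07), TNIK (3.76) and PDE4B (3.56) higher in KO2 and KRT7 (−3.99), KRT80 (−3.29) and F3 (−2.79) lower. A difference between their library sets, if any, cannot be told apart from the clone there. ERCC counts, in CPM of gene counts, were 1326 and 1328 in 4sU KO1 replicates 2 and 3, above the 714 to 831 of the 4sU controls, within which replicate 1 lay (809.9). They were 5945 and 6434 in siKAP1 replicates 2 and 3, above the 33.9 to 541 of siNT, within which replicate 1 lay (74.3).

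Each count of genes was set against other splits of the same libraries, fitted by edgeR. For 3 against 3 libraries there are only 10 splits, too few for a share under 0.05. The real split alone (1 of 10) reached its count in KO1 nascent RNA (2807), KO1 steady-state RNA (8922), KO2 steady-state RNA (7806), siKAP1 (6958) and KO2 against KO1 (7604), and the highest other split gave 0 calls each time (at unadjusted p under 0.05, at most 2723, 100, 80, 524 and 185 genes in that order). Every other split puts libraries of both real groups on each side, so a real difference enters the spread within groups and holds calls down. These counts of 0 therefore do not speak against chance. For siKAP1 minus KO1, 1 of 100 splits gave 7586 genes, and the highest other gave 3258. There too, 21 splits keep 1 grouping, and the 78 that mix both gave at most 0 calls (496 unadjusted). For nascent minus steady-state RNA in KO1, 4 of 100 splits gave at least 1977 genes, and the highest other gave 5061. Of those 100 splits, 21 keep the real grouping of an assay and mix only the other, so they carry the whole KO1 effect of that assay, and the 78 that mix both gave at most 0 calls (2426 genes at unadjusted p under 0.05). A split that keeps 1 grouping calls many genes because it holds a real difference in 1 assay. In splits that mix both, real differences again enter the spread, so their 0 calls do not speak against chance.

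KRAB zinc finger genes were higher in both clones (medians 0.43, which became −0.09 with ERCC scaling, 0.59, 0.41 and 0.50) and not after siKAP1 (−0.15). The lower depth of the siRNA set was excluded as the cause, since KO1 steady-state counts thinned to that depth still gave 86 of 129 members higher, against 10 of 121 after siKAP1. Expression level and gene length were excluded too, since the list median lay at percentile 100 of 10000 matched random lists in each knockout comparison. A gain of the whole of chromosome 19 was excluded, since the other genes of that chromosome reached at most 34.6% of the list median, though a gain limited to zinc finger clusters was not tested. The biological alternative, that lasting loss of KAP1 acts differently from 72 h of knockdown, remains open, because clone, time, method and library set changed together. TRIM28 RNA also differed, at 13.1% of its control after siKAP1 and at 3.91% and 10.4% in the steady-state RNA of KO1 and KO2. KAP1 protein was not measured in these libraries, so these values do not give the degree of KAP1 loss.

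The p53 targets were higher in both clones (medians 0.64, or 0.13 with ERCC scaling, 0.50, 0.71 and 0.49) and lower after siKAP1 (−0.29). Depth was excluded, since thinned KO1 counts gave 32 members higher, and so were expression level and gene length, with a percentile of 100 among matched lists. Slower proliferation cannot be told apart from a direct effect in either clone, since cell cycle genes went both ways in steady-state RNA, with 29 of 56 higher and 9 lower in KO1 (median 0.0947, camera adjusted p = 0.0247 upward, and 0.722 with an estimated correlation) and 8 higher and 24 lower in KO2 (median −0.176, camera adjusted p = 0.121). A rise of p53 activity in cells that live without KAP1 remains open, since unedited cells differed as well. CDKN1A stood at 190.04 CPM in siNT cells against 99.0 in the control of the clones. The siNT cells received an siRNA and came from another library set, so this difference cannot be given to either.

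Short genes were lower and long genes higher in KO2 nascent RNA (short minus long −0.75). Control 2 replicate 2 alone cannot be told apart from other causes, since −0.329 remained without it, less than the largest difference between replicates elsewhere. By the limit fixed beforehand, −0.329 would have counted against that library alone. The allowance for differences between replicates was added after the results were seen, and the fit without that library leaves 1 control library. KO2 cells in control 2 replicate 1 were excluded, since genes switched on in the knockout stood there at a median of 1.29% of their KO2 level, where its TRIM28 level would need 64.3%. Differences between libraries unrelated to genotype could produce the trend, since 4sU KO1 replicates 1 and 3 differ from each other by 0.789 on the same measure, and the ribosomal protein and histone falls in KO2 nascent RNA are therefore open. No biological explanation of the trend was tested.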

How the results depend on the processing

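The gene length correction was chosen only after the results were seen. Of the fold changes of named genes compared with an alternative, 3094 kept their reading, 47 became stronger, 110 weaker and 22 reversed. Where leaving out a library left a single sample, that sample was assumed to vary like the other groups. Thinned to the depth of the siRNA set, KO1 steady-state RNA gave 7581 calls against 8922.

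With the replicate number as a block, calls were 1622 in KO1 nascent RNA, 4632 in KO2 nascent RNA (48.3% higher), 659 for nascent minus steady-state RNA and 237 for KO2 minus KO1 nascent, and 9248, 8670 and 8817 in KO1 steady-state RNA, siKAP1 and siKAP1 minus KO1. Between libraries with the same number, correlations of deviations were −0.61, 0.20 and −0.11 in KO1 nascent RNA, −0.02, −0.03 and 0.11 in KO1 steady-state RNA, 0.37, 0.36 and 0.04 in the siRNA set (−0.38 to 0.00436 between unlike numbers) and 0.19 and 0.19 in KO2 nascent RNA (−0.19 between unlike numbers). With 2 libraries per group the deviations mirror each other, so the KO2 nascent values are 1 number with its sign changed. Whether the numbers mark pairs is open for the siRNA set and KO2 nascent RNA. No paired analysis was run for KO2 steady-state RNA against control or KO1, because the numbers in its column names were judged ambiguous. ERCC scaling was not run for the KO2 comparisons or for differences between effects.

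A 2-fold limit left 944 genes in KO1 nascent, 1053 in KO1 steady-state, 1547 in KO2 steady-state, 838 in siKAP1, 284 in nascent minus steady-state, 1721 in siKAP1 minus KO1 and 1444 in KO2 against KO1. Shared calls higher and lower were then 235 and 310 for KO1 nascent and steady-state, 258 and 250 for KO1 and KO2 steady-state, 238 and 188 for KO1 and KO2 nascent, 13 and 120 for KO1 and siKAP1, and 355 and 173 for KO2 nascent and steady-state. For KO1 and siKAP1, 38 and 23 were then opposite (13.4 and 7.47 expected), above chance, where without the limit opposite calls lay below it. The stricter filter gave 1531 in KO1 nascent, 210 in KO2 nascent and 259 in KO2 minus KO1 nascent. Without any filter, 62.5% of the nascent minus steady-state calls were higher, against 47.1%. DESeq2 gave 3381 calls in KO2 nascent and 2653 in KO2 minus KO1 nascent, 602 shared lower genes for KO1 and KO2 nascent, and 1006 and 1091 shared higher and lower for KO2 nascent and steady-state. The fit over all libraries of the assay gave 4420 in KO2 nascent. Gene length correction gave 2668 in KO2 nascent, 3189 in nascent minus steady-state and 1405 in KO2 minus KO1 nascent, and turned SMAD2 to 0.0428 in KO1 steady-state and −0.00130 in KO2 nascent, and CDK9 to −0.0504 in KO1 nascent, 0.0310 in KO2 nascent and 0.0735 in KO2 minus KO1 nascent.

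ERCC scaling turned CDK9 (−0.51), SMAD3 (−0.0273) and HEXIM1 (−0.12) in KO1 nascent RNA. In siKAP1 it left 0 calls by edgeR (6 at unadjusted p under 0.05; DESeq2 35) and turned SMAD2 (−2.10), CDK9 (−1.90), ZNF425 (−1.39), CTR9 (−1.14), NELFCD (−1.48), AFF4 (−1.76), SUPT5H (−1.56), MT-ND2 (−0.66), MT-ND3 (−0.84), MT-ND5 (−1.26) and MT-ND1 (−1.30).

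Lists called by camera numbered 7, 12, 9, 7, 12, 9, 6, 8 and 9 in KO1 nascent, KO1 steady-state, KO2 steady-state, KO2 nascent, siKAP1, nascent minus steady-state, KO2 minus KO1 nascent, siKAP1 minus KO1 and KO2 against KO1. With an estimated correlation they numbered 1, 0, 0, 0, 0, 2, 0, 1 and 0 (2, 4, 3, 1, 3, 4, 2, 4 and 1 at unadjusted p under 0.05). Fry in its directional form called 20 in KO1 steady-state, 19 in KO2 steady-state, 0 in KO2 nascent (5 unadjusted), 20 in siKAP1 minus KO1 and 19 in KO2 against KO1. Its mixed form called 21 in KO1 nascent, 24 in KO1 steady-state, KO2 steady-state, siKAP1 and KO2 against KO1, 19 in nascent minus steady-state, 18 in KO2 minus KO1 nascent and 25 in siKAP1 minus KO1.

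Leaving out each library in turn gave 1662 to 3599 calls in KO1 nascent, 8293 to 8726 in KO1 steady-state, 6641 to 8214 in KO2 steady-state, 908 to 11057 in KO2 nascent, 5763 to 6744 in siKAP1, 1022 to 2977 in nascent minus steady-state, 171 to 6123 in KO2 minus KO1 nascent, 7027 to 7751 in siKAP1 minus KO1 and 6334 to 8277 in KO2 against KO1. CDK9 ranged from −0.0903 to 0.0906 in KO1 nascent RNA and SMAD2 from −0.0285 to 0.435 in KO2 nascent RNA. Why single libraries moved these counts was not tested.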

Other observations

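The hypothesis about the control cells and its test were chosen only after the results were seen.

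The KRAB zinc finger genes on chromosome 19 moved more than those elsewhere. In KO1 steady-state RNA the 97 members on chromosome 19 had a median log2 of 1.01 and the 46 elsewhere 0.05, and in KO2 steady-state RNA the medians were 0.61 (94 members) and 0.04 (46). In nascent RNA they were 0.62 (112) and 0.02 (46) in KO1, relative to the typical gene (the whole list became −0.09 with ERCC scaling), and 0.75 (113) and 0.16 (46) in KO2. After siKAP1 they were −0.16 (80) and −0.13 (41). These differences were not tested. ZNF595 on chromosome 4 (53284 to 88211) and ZNF736 on chromosome 7 (64307458 to 64354860) rose in the clones although they lie elsewhere.

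CPA4 moved in opposite directions between comparisons, and NT5E changed to different extents between assays. CPA4 fell in KO2 steady-state RNA (82.5 to 4.88 CPM) and rose after siKAP1 (2.34 to 15.6 CPM). NT5E fell in KO1 steady-state RNA (−2.12 ± 0.04), and the KO1 effect on its nascent RNA was higher by 1.36 ± 0.10, less than the size of that fall. CHAC1 and ASNS, targets of the amino acid stress response, fell in KO2 nascent RNA and after siKAP1, though both nascent calls were lost without KO2 replicate 1 or 2, and CHAC1 became −0.47 (adjusted p = 0.102) after the gene length correction. Shared falls of SLPI and FOXQ1 rest on few counts in the lower group, 8 and 3 in KO1 steady-state RNA and 3 and 10 after siKAP1.

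Median, mean and camera direction did not all share a sign for a few lists, none of them called by camera. These were TGF-beta targets, pausing and elongation factors, silencing factors, stress response genes and MCF7 markers in KO1 nascent RNA, hypoxia, cholesterol synthesis and mitochondrially encoded genes in KO1 steady-state RNA, MCF7 markers in KO2 steady-state RNA, and TGF-beta targets, MAPK output genes and EMT genes after siKAP1. Among differences, they were germline, immediate early and intestinal genes for nascent minus steady-state RNA, imprinted, germline, p53, cholesterol synthesis, EMT and intestinal genes for KO2 minus KO1 nascent, germline, immediate early, silencing and fibroblast marker genes for siKAP1 minus KO1, and MAPK output genes, EMT genes and MCF7 markers for KO2 against KO1.

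TRIM28 differed between the control 2 libraries by a log2 of −1.36, beyond the median of −0.55 of 611 genes of like length, of which 0.327% lay at or below it. Short genes differed from long genes by −0.898 between the control 2 libraries and by −0.0175 between the KO2 libraries. Without control 2 replicate 1 the short minus long difference of KO2 nascent RNA was −1.15, and without KO2 replicate 1 or 2 it was −0.76 or −0.78.

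Unedited siNT cells from the siRNA set stood apart from the unedited controls of the clones. With all steady-state libraries scaled together by TMM, CDKN1A had 99.0 CPM in controls and 190.04 in siNT, GDF15 36.5 and 185, SPARC 0.106 and 2.06, ZNF595 0.0414 and 4.46, and TAGLN 77.9 and 2.95. ACTL8 (0.973 and 0.0626) and ZNF569 (0.0206 and 0.0146) were near silence in both. A hypothesis was that genes higher in the clones were low in these control cells rather than raised by the knockout. Of 258 genes at least 2-fold higher in the steady-state RNA of both clones, 52.7% were nearer the clones than the control in siNT cells. This cannot be told apart from a difference between library sets or from an effect of the siRNA that siNT cells received. Among the 36 KRAB zinc finger genes of that set, 19.4% (7 genes, ZNF595 among them) were nearer the clones and 29 nearer the control. A low control level would not account for those 29. The same possible differences in library set and siRNA treatment apply, so low control levels were not excluded. Of 250 genes at least 2-fold lower in both clones, 26.4% were nearer the clones in siNT cells.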
